A study of Mus musculus with 14 samples.

How the data were processed

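Total RNA from mouse embryonic stem cells and epiblast stem cells was sequenced after ribosomal RNA depletion as single-end 100 bp reads, per the labels' protocols. The deposited files hold 1 FPKM value, a fragment count scaled to transcript length and library size, per feature in each of 14 libraries. The authors named TopHat2 2.0.10, Bowtie2 2.1.0 and Cufflinks 2.1.1 and the mouse genome build mm9, per the submitters' processing notes; which of these made the FPKM values, and whether values were scaled between libraries, is not stated there. Gene symbols and mm9 positions were used as the deposited files give them, and the reference annotation of a later build was not used for positions.

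FPKM of features that shared a gene symbol were summed (411 features with 163 repeated symbols, leaving 22926 symbols), and 204 features that carry several symbols were kept as 1 feature. A gene was tested when it reached 1 FPKM in at least 2 of the 12 libraries of the 6 genotype and culture groups, which left 11584 genes. Values were analysed as log2(FPKM + 1), which draws the fold changes of genes near or below 1 FPKM toward 0. FPKM hold no read totals, so the precision from read counts is unknown. A relative depth per library was estimated from the spacing of the lowest values. It ran from 0.497 to 3.01 of that of WT SL replicate 1 and was unclear in 3 libraries, among them the one at 0.497. Features listed at 0 in some libraries and at 1000 FPKM or more in others, among them Eef1a1 and Rn45s, were read as failed estimates and not named.

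One limma 3.58.1 model in R 4.3.3 with a mean for each of the 6 groups was fitted to the 12 libraries (lmFit, then eBayes with an intensity trend; 6 residual degrees of freedom), so that groups with 2 libraries share 1 estimate of the spread per gene. From it came 9 contrasts: KO against WT in SL, 2iL and FA; 2iL and FA against SL in WT and in KO; and the 2 differences between KO and WT in these culture changes. A further limma fit compared the means of the 4 cell lines over the 3 cultures. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Since each replicate number stands for a separate cell line, the p-values measure the spread between lines. The 12 libraries came from only 4 lines, and the model of 6 groups took the libraries of a line as independent. For KO against WT its p-values thus rest on fewer independent values than the 6 residual degrees of freedom count. Its spread per gene also covers both genotypes, although the KO lines lay further apart than the WT lines. That spread can be too small for KO and too large for WT. An exact permutation test of 2 against 2 cannot give a p below 0.333.

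Genes were named by a rule fixed before the files were read: for each KO against WT contrast the 10 largest log2 fold changes in each direction among genes that passed, had a mean of at least 5 FPKM in the higher group and did not overlap in range between the groups. It took 8 in each direction for culture changes and 5 for the differences and for the line means. Predicted genes and small RNAs were tested but not named. Where fewer than 5 passed, the 5 of lowest p in that direction were named as not passing. Members of fixed lists could always be named. For the 2 single libraries it took the 8 largest differences in each direction, without a test.

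The 20 gene lists were also fixed beforehand. Only members that passed the filter on expression were tested, and counts of members called are out of these. Tested were 5 of 11 trophectoderm, 6 of 12 fibroblast, 7 of 11 primitive streak, 5 of 11 primitive endoderm and 3 of 10 2-cell-like genes. Results for these lists therefore do not cover the whole lists. The lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each adjusted p is given beside that from camera with an estimated correlation. Calls of single members were counted with the adjustment over all genes and with an adjustment over the list alone. EpiSC and long-term 2iL cells, with 1 library each, were compared as log2 differences, with each list's median set among 10000 random lists of the same size matched on mean expression. Correlations of changes were taken across genes.

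The scripts were tested on simulated log2 values made from the measured means and spreads, with known changes. Each gene had 1 spread in all 12 libraries, so these checks do not cover the unequal spread of the KO and WT lines. No culture change in KO was simulated. For KO against WT in SL, with 195 changed genes among 11149, 88.8% of 4-fold and 12.4% of 2-fold changes were recovered with 2 false calls among 101. For 2iL against SL in WT, with 192 changed genes among 11135, the shares were 86.3% and 17.5% with 5 false calls among 104. With a correlation of 0.6 between the libraries of a line, the shares were 78.8% and 10.0% for the first (6 false calls among 94), 81.6% and 12.2% for the other (0 among 92), and 88.0% and 9.28% for the 4 line means (6 among 103). Without changed genes there were 0 calls in each. Changes near 2-fold were thus mostly missed at this number of replicates. Of 100 lists without an effect, camera gave 2 an unadjusted p below 0.05. The simulated genes varied independently of one another, so this does not show how the preset correlation serves lists whose members vary together.

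The settings varied were a pseudocount of 0.1, no filter on low values, quantile normalization, median-ratio scaling, small-RNA names left out, the highest feature per symbol in place of the sum, eBayes without trend, an added minimum absolute log2 fold change of 1, only the libraries of the groups compared, a replicate block (also in camera), each library left out in turn and, for the line means, all 12 libraries in one fit. Leaving out failed estimates was added later. The pairing was checked by correlating the deviations of libraries from their group means. For culture changes the block was the cell line, which is the same in each culture, and its values are given beside those results. For KO against WT the block was the replicate number, which different lines share.

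Left out were 2 sex-linked genes that the rules would have named and the small RNAs, apart from a pair of microRNA features named because few features were called. One further member of a fixed list is not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3, and tables were handled with jsonlite 2.0.0 and data.table (version 1.17.8).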

Results

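Transcript abundance was measured by RNA sequencing after ribosomal RNA removal in 14 libraries of mouse pluripotent stem cells. Embryonic stem cells of 2 genotypes, wild type (WT) and null for the zinc finger protein gene Zfp281 (KO), were each grown in 3 cultures, with 2 libraries per group. SL held 15% serum and 1000 units per mL of leukemia inhibitory factor (LIF). 2iL was a serum-free medium with the Gsk3 inhibitor CHIR99021 at 3 µM, the MEK inhibitor PD0325901 at 1 µM and LIF, applied for 48 h. FA was the same base medium with activin A at 20 ng/mL and Fgf2 at 12 ng/mL, also applied for 48 h. Replicate 1 was line CJ7 in WT and line 3.34-/- in KO. Replicate 2 was line 3+/+ in WT and line 7-/- in KO, so each of the 4 lines was present in all 3 cultures. The remaining 2 libraries were an epiblast stem cell (EpiSC) line kept in FA and CJ7 cells kept in 2iL for more than 16 days.

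Every library held an FPKM value, a read count scaled to transcript length and library size, for the same features, of which 10168 to 10677 reached 1 FPKM. Read totals cannot be read from FPKM, so depth was taken only as a ratio to WT SL replicate 1, from the spacing of the lowest values. That ratio ran from 0.497 to 3.01, and the spacing was not clear in 3 libraries, KO SL replicate 1, WT FA replicate 1 and WT FA replicate 2. The low end, 0.497, was the unclear value of KO SL replicate 1, and the lowest clear value was 0.642, in the EpiSC library. KO SL replicate 1 stood apart: the 2 structural RNAs Rmrp and Rpph1 made up 25.3% of its summed FPKM, against 1.65% to 12.0% elsewhere. Pearson's r between the replicates of a group, across genes that are not independent replicates, was 0.981 in WT SL, 0.950 in KO SL, 0.984 in WT 2iL, 0.964 in KO 2iL, 0.967 in WT FA and 0.939 in KO FA. The KO lines thus differed more from each other than the WT lines did: 1605 genes lay over 2-fold apart between them in FA, against 318 between the WT lines. Replicates are separate cell lines, so p-values measure the spread between lines. An exact permutation test of 2 against 2 cannot go below 0.333. Genotype and line cannot be separated within this design, because no line was measured both with and without Zfp281.

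The targeted gene was lower in all KO libraries. Zfp281 (chromosome 1, 138521477 to 138526968, mm9) stood at 24.8 and 20.99 FPKM in the WT SL libraries, 17.2 and 17.3 in WT 2iL, and 25.6 and 23.8 in WT FA. Line 3.34-/- held 0.0585, 0.0701 and 0.602 FPKM in SL, 2iL and FA. Line 7-/- held 5.08, 2.30 and 4.61 FPKM, which was 24.2%, 13.3% and 19.4% of the WT library with the same replicate number. The labels do not say which part of the gene was removed, and whether the transcript left in line 7-/- encodes protein was not measured. Although lower in each KO library, Zfp281 itself was not called by limma in KO against WT in SL, 2iL or FA. The paralogue Zfp148 was not called in any of the 3 cultures either, at 3.23 ± 0.450 FPKM in WT SL and 4.59 ± 0.639 in KO SL (mean ± SD, n = 2).

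**Figure D1:**
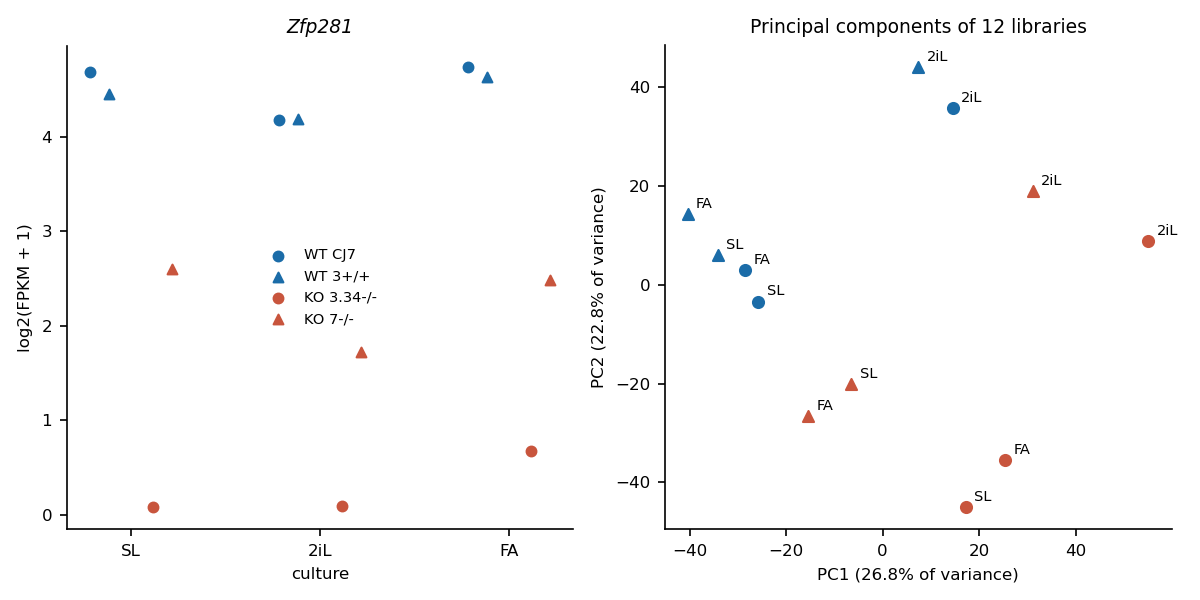
Left, Zfp281 as log2(FPKM + 1) for each of the 12 libraries by culture, with colour for genotype and symbol for line. Right, the first 2 principal components of log2(FPKM + 1), which held 26.8% and 22.8% of the variance. The WT SL and WT FA libraries lie together, and both KO lines lie apart from them.

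The comparison of KO with WT in SL addresses what the loss of Zfp281 changes in serum-grown cells. Tagln had the largest fall of the genes named by rule, and Acta1 and 3 keratin genes were among the others. Tagln, which encodes the actin-binding protein transgelin, fell from 90.4 ± 8.35 FPKM in WT to 1.14 ± 0.309 in KO (mean ± SD, n = 2; log2 fold change -5.42, SE 0.23, adjusted p = 4.01e-06, limma with Benjamini-Hochberg adjustment). Krt8 and Krt18, the keratin pair of simple epithelia, fell from 262 ± 9.004 to 22.1 ± 3.98 FPKM (log2 fold change -3.52, SE 0.35, adjusted p = 7.93e-04) and from 192 ± 23.9 to 11.5 ± 2.96 FPKM (log2 fold change -3.96, adjusted p = 0.00347). Krt19, another keratin of simple epithelia, fell from 149 ± 39.2 to 12.6 ± 12.2 FPKM (log2 fold change -3.80, adjusted p = 0.00683). Acta1, skeletal alpha-actin, fell from 21.1 ± 5.61 to 0.0419 ± 0.0593 (log2 fold change -4.39, adjusted p = 3.51e-05). Gpx2, a glutathione peroxidase, rose from 1.75 ± 0.945 to 46.6 ± 7.81 FPKM (log2 fold change 4.15, SE 0.38, adjusted p = 5.30e-04).

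Among the other falls in SL were Igfbp3, which encodes a carrier of insulin-like growth factors (107 ± 4.75 to 4.203 ± 2.44 FPKM, log2 fold change -4.46, adjusted p = 5.30e-04), and the annexin gene Anxa3 (27.6 ± 5.003 to 0.637 ± 0.217, log2 fold change -4.13, adjusted p = 1.81e-04). Gbp1 (59.5 ± 19.05 to 2.28 ± 3.00 FPKM), Gbp2 (70.0 ± 17.4 to 3.05 ± 3.76) and Psmb8 (34.8 ± 7.46 to 1.42 ± 1.26) fell too. Their log2 fold changes were -4.56, -4.52 and -3.97. Among the rises were the neural transcription factor gene Olig2 (0.0241 ± 0.00544 to 8.35 ± 5.96 FPKM, log2 fold change 3.03, adjusted p = 0.00252). Others were the testis cytochrome c gene Cyct (log2 fold change 3.04, adjusted p = 0.00580), Tstd1 (log2 fold change 3.67, adjusted p = 0.00872) and Gc, the vitamin D binding protein gene (log2 fold change 3.24, adjusted p = 0.00196). Ubd, a ubiquitin-like modifier gene, was listed at 0 in both WT libraries and stood at 29.2 and 5.30 FPKM in the KO libraries (adjusted p = 0.0322). Nlrp4f, the homeobox gene Nkx6-3, the innate immune receptor gene Nod1 and the histidine ammonia-lyase gene Hal also rose, with log2 fold changes of 2.92, 2.61, 2.60 and 2.58. Fold changes were taken on log2(FPKM + 1), which understates those of genes near or below 1 FPKM.

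Of the 20 gene lists fixed beforehand, 5 passed the camera test in SL, all lower in KO, and none kept its call with an estimated correlation. The trophectoderm list fell (adjusted p = 2.11e-06, or 0.0530 with an estimated correlation). Of its 11 members 5 were tested, and 4 of these fell, Cdx2, Krt7, Krt8 and Krt18. The 4 also passed when adjusted over the list alone. The fibroblast list fell (adjusted p = 5.88e-05, or 0.0530 with an estimated correlation), with 3 of 6 members lower, and 4 when adjusted over the list alone. Of these, Tagln and the smooth muscle actin gene Acta2 (4.21 ± 0.469 to 0.121 ± 0.116 FPKM) are contractile genes, while the collagen gene Col1a2 moved at a low level, from 0.730 ± 0.0399 to 0.0270 ± 0.0382 FPKM. The primitive streak and mesendoderm list fell (adjusted p = 3.52e-04, or 0.197 with an estimated correlation), with 3 of 7 members lower by either adjustment. These were T (Brachyury), Wnt3 and Fgf8, at log2 fold changes of -2.18, -2.57 and -1.45. The list of primed and formative pluripotency fell (adjusted p = 0.00126, or 0.339 with an estimated correlation; median log2 fold change -1.32), with 2 of 12 members lower by either adjustment, the kinase gene Pim2 (19.9 ± 7.46 to 5.02 ± 0.887 FPKM) and the claudin gene Cldn6 (64.5 ± 1.81 to 20.0 ± 8.07). Imprinted genes were lower as a list (adjusted p = 0.00988, or 0.119 with an estimated correlation), with 1 of 15 members called, the growth-limiting RNA H19 (84.4 ± 8.85 to 9.24 ± 0.290 FPKM), and 2 when adjusted over the list alone. Without KO SL replicate 1 the list's adjusted p was 0.0917. Outside these lists, the RNA-binding protein gene Lin28a fell from 158 ± 7.91 to 31.8 ± 12.6 FPKM (log2 fold change -2.33, adjusted p = 0.00233). The intermediate filament gene Nes fell from 14.1 ± 2.63 to 0.949 ± 1.23 (log2 fold change -3.11, adjusted p = 0.00264). The naive factor gene Nr0b1 rose from 54.0 ± 7.24 to 147 ± 9.01 (log2 fold change 1.43, adjusted p = 0.0369). The naive list itself, with 1 of 15 members called and 2 when adjusted over the list alone, was not called (adjusted p = 0.297).

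Limma called 378 of 11584 genes in SL, 118 higher and 260 lower in KO. Of the 20 genes named by rule, 10 kept their call in all 15 alternatives. The count was 148 without KO SL replicate 1, the library rich in Rmrp and Rpph1, 56 without WT SL replicate 1, 70 without WT SL replicate 2 and 562 without KO SL replicate 2. The calls of Gbp1, Gbp2, Psmb8, Tstd1, Cyct, Ubd, Nkx6-3, Nod1, Hal and Krt19 were lost in at least 1 of these.

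In 2iL, where MEK and Gsk3 are inhibited, the largest falls in KO were in embryonic globin genes. Hbb-bh1 was 41.1 ± 9.28 FPKM in WT 2iL, and the KO 2iL libraries held 0.0578 and 0 (mean ± SD, n = 2, for WT; log2 fold change -5.34, SE 0.32, adjusted p = 6.93e-05). Hbb-y was 12.7 ± 0.253 FPKM in WT 2iL and was listed at 0 in both KO 2iL libraries (adjusted p = 8.47e-06). Lin28a fell from 66.6 ± 0.259 to 9.67 ± 1.96 FPKM (log2 fold change -2.67, SE 0.28, adjusted p = 0.00258). T fell from 6.02 ± 0.0698 to 0.407 ± 0.456 (log2 fold change -2.36, adjusted p = 0.00258). AA467197, a gene of unsettled function, rose from 15.9 ± 2.40 to 206 ± 97.9 FPKM (log2 fold change 3.54, SE 0.37, adjusted p = 0.00258). The cell cycle regulator gene Rgcc rose from 2.43 ± 0.282 to 35.6 ± 19.4 (log2 fold change 3.31, adjusted p = 0.00242).

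Several genes that differed in SL also differed in 2iL. Tagln fell from 7.67 ± 0.406 to 0.256 ± 0.0614 FPKM (log2 fold change -2.79, adjusted p = 6.53e-04), Krt19 from 17.8 ± 4.16 to 0.813 ± 0.491 (log2 fold change -3.38, adjusted p = 0.0239) and Igfbp3 from 17.6 ± 0.555 to 3.13 ± 2.26 (log2 fold change -2.29, adjusted p = 0.0323). Gpx2, Olig2 and Cyct rose again, with log2 fold changes of 2.52, 2.88 and 2.90. Further rises were in the glutamine transporter gene Slc1a5 (5.35 ± 1.47 to 32.3 ± 11.3 FPKM, log2 fold change 2.36, adjusted p = 0.0192) and the glutathione transferase gene Gsto1 (log2 fold change 2.85, adjusted p = 0.0213). Also higher were the fatty acid receptor gene Ffar3 (log2 fold change 2.75), Tmem40 (log2 fold change 2.68) and Crisp1 (log2 fold change 2.37). Further falls were in the carbonic anhydrase gene Car2 (34.3 ± 2.87 to 6.20 ± 4.47 FPKM, log2 fold change -2.45, adjusted p = 0.0219), Efhc2 (log2 fold change -2.37) and Plac8 (log2 fold change -2.34).

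By the camera test 6 lists passed in 2iL, and none did so with an estimated correlation. Germline genes that are silenced by DNA methylation in somatic cells rose as a list (adjusted p = 0.0142, or 0.612 with an estimated correlation), with 1 of 13 members called, Dazl (6.29 ± 2.26 to 26.7 ± 8.16 FPKM), and 3 when adjusted over the list alone. Primitive streak genes fell (adjusted p = 0.00540, or 0.323 with an estimated correlation), with T, Wnt3 and Fgf8 again the 3 called of 7. When adjusted over the list alone the 3 stayed and Gsc, at log2 fold change 1.05, passed in the other direction. Fibroblast genes fell (adjusted p = 0.00461, or 0.249 with an estimated correlation) with Tagln the 1 member called of 6, and 3 when adjusted over the list alone. The trophectoderm list fell (adjusted p = 0.0474, or 0.323 with an estimated correlation) with 0 of 5 members called, and 1, Krt18, when adjusted over the list alone. Glycolysis genes (adjusted p = 0.00211, or 0.249 with an estimated correlation) and p53 targets (adjusted p = 0.00461, or 0.249 with an estimated correlation) fell as lists with 0 members called among 13 and 11, and with 1 and 0 when adjusted over the list alone. Their median log2 fold changes were -0.51 and -0.53. The DNA demethylation enzyme gene Tet2 stood at 6.90 ± 0.188 FPKM in WT and 20.7 ± 1.76 in KO and passed only when adjusted over its list alone, as did the methylation cofactor gene Dnmt3l, at 23.5 ± 3.75 and 5.83 ± 6.41 FPKM.

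Limma called 103 genes in 2iL, 52 higher and 51 lower in KO. Of the 20 genes named by rule, 7 kept their call in all 15 alternatives. The count was 12 without WT 2iL replicate 1, 16 without WT 2iL replicate 2 and 48 without KO 2iL replicate 1. The germline call was lost without WT 2iL replicate 1 (adjusted p = 0.278) and without KO 2iL replicate 1 (0.137), and the glycolysis call without KO 2iL replicate 2 (0.0683). The trophectoderm call was lost in 6 of 7 alternatives. Beside the estimated correlation these were without WT 2iL replicate 1 (0.229), KO 2iL replicate 1 (0.197) or KO 2iL replicate 2 (0.0683), with a replicate block (0.0605) and with a pseudocount of 0.1 (0.0527).

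In FA, the culture that drives cells toward the primed state, mesendoderm genes that WT cells transcribed fell in KO cells. T fell from 9.12 ± 0.772 FPKM in WT to 0.170 ± 0.169 in KO (mean ± SD, n = 2; log2 fold change -3.12, SE 0.25, adjusted p = 1.95e-04, limma). Gsc (goosecoid) fell from 9.60 ± 2.79 to 0.292 ± 0.413 (log2 fold change -3.05, SE 0.36, adjusted p = 0.00219). Fgf8, which encodes a growth factor of the gastrula, fell from 8.17 ± 2.24 to 0.156 ± 0.122 FPKM (log2 fold change -2.97, adjusted p = 1.39e-04). Wnt3 fell from 7.86 ± 0.346 to 0.316 ± 0.0253 (log2 fold change -2.75, adjusted p = 6.14e-05). Cer1, which encodes a secreted Nodal antagonist, fell from 6.28 ± 0.227 FPKM to 0.0203 and 0 in the KO libraries (log2 fold change -2.85, adjusted p = 9.87e-06).

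Tagln fell again in FA (47.9 ± 2.55 to 2.85 ± 0.790 FPKM, log2 fold change -3.68, adjusted p = 3.61e-05). The falls of Krt19 (log2 fold change -3.56, adjusted p = 0.0105), Igfbp3 (log2 fold change -3.02, adjusted p = 0.00463), Anxa3 (log2 fold change -2.86, adjusted p = 9.02e-04) and Lin28a (206 ± 8.26 to 26.2 ± 4.001 FPKM, log2 fold change -2.94, adjusted p = 7.16e-04) recurred as well. Rises were led by Gpx2 (1.73 ± 1.12 to 55.8 ± 13.4 FPKM, log2 fold change 4.42, adjusted p = 4.04e-04) and the stress-responsive gene Nupr1 (4.59 ± 1.46 to 73.0 ± 33.4, 3.68, adjusted p = 0.00151). Slc1a5 (4.97 ± 1.99 to 53.9 ± 20.2 FPKM, 3.19, adjusted p = 0.00207) and Dhrs7 (4.79 ± 1.09 to 53.5 ± 33.3, 3.10, adjusted p = 0.00576) rose too. Tstd1, Olig2, Sept1, Fam129a and Cyct also rose, with log2 fold changes of 3.46, 2.97, 2.83, 2.78 and 2.67. So did Ifitm3 (log2 fold change 2.80).

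The camera test passed 6 lists in FA, of which 2 kept their call with an estimated correlation. Primitive streak and mesendoderm genes fell as a list (adjusted p = 2.04e-14, or 0.0244 with an estimated correlation). In that list 6 of 7 members were called lower, T, Gsc, Fgf8, Wnt3, Mixl1 (log2 fold change -1.77) and Foxa2 (log2 fold change -2.02), and all 7, Eomes included, when adjusted over the list alone. Fibroblast genes fell (adjusted p = 6.63e-06, or 0.0244 with an estimated correlation), with Tagln, Acta2 and Col1a2 the 3 called of 6 by either adjustment. Col1a2 went from 2.46 ± 0.416 to 0.0423 ± 0.0313 FPKM. Nodal and Activin genes fell as a list (adjusted p = 0.00200, or 0.0641 with an estimated correlation), with Cer1 called, 1 of 8, and 2 when adjusted over the list alone. The trophectoderm list fell (adjusted p = 0.0417, or 0.343 with an estimated correlation), with Krt8 called, 1 of 5 by either adjustment. Naive genes rose as a list (adjusted p = 0.00887, or 0.679 with an estimated correlation), with 1 of 15 members called, Nr0b1 (33.8 ± 9.85 to 113 ± 25.8 FPKM), and 3 when adjusted over the list alone. Primed and formative genes fell as a list (adjusted p = 0.0462, or 0.679 with an estimated correlation) with 0 of 12 members called, and 2 when adjusted over the list alone. Other called members of fixed lists were Tet2, which rose from 2.13 ± 0.353 to 12.2 ± 8.97 FPKM (log2 fold change 1.90, adjusted p = 0.0347). Nes and the cyclin gene Ccnd1 fell (log2 fold changes -2.14 and -1.63).

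The KO lines differed from each other in FA. Naive transcripts were higher in line 3.34-/- than in line 7-/-: Klf4 was 38.1 against 0.890 FPKM and Esrrb 50.7 against 7.93, where the WT libraries held 6.89 and 2.46 and 14.2 and 7.41. Primed transcripts were lower in line 3.34-/-: Dnmt3b was 27.1 against 201 FPKM, Fgf5 0.804 against 5.70 and Wnt8a 0.0754 against 6.12, where the WT libraries held 249 and 167, 6.59 and 4.38 and 3.51 and 5.40. Over the whole lists the gaps were smaller. The median log2 difference in FA, line 3.34-/- minus line 7-/-, was 1.67 for naive and -0.997 for primed genes. T, Wnt3, Fgf8 and Cer1 were low in both KO lines, and the highest value of these 4 genes was 0.334 FPKM, for Wnt3 in line 3.34-/-.

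Limma called 309 genes in FA, 129 higher and 180 lower in KO. Of the 20 genes named by rule, 13 kept their call in all 15 alternatives. The count was 95 without WT FA replicate 1, 77 without WT FA replicate 2 and 577 without KO FA replicate 2. Without KO FA replicate 1, which is line 3.34-/-, the naive list's test changed direction (adjusted p = 0.748) and the primed list's call was lost (adjusted p = 0.666). The primed call was also lost without WT FA replicate 1 (0.710), and the trophectoderm call without either of these libraries (0.210 without WT FA replicate 1, 0.230 without KO FA replicate 1). With a replicate block the 2 lists stood at 0.110 and 0.0538, and with a pseudocount of 0.1 the primed list stood at 0.0683.

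**Figure D2:**
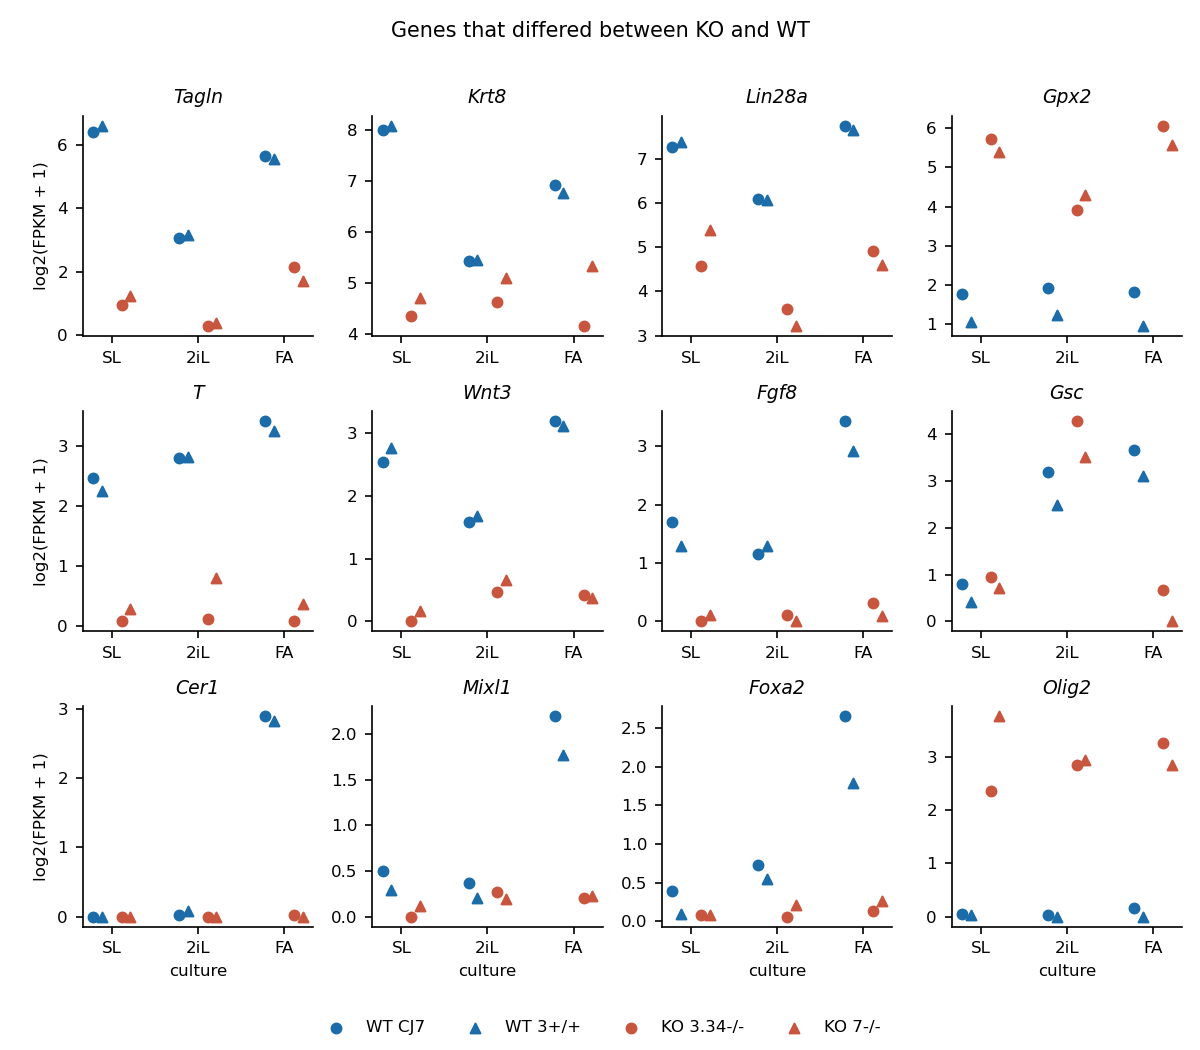
Each panel plots log2(FPKM + 1) of 1 gene in the 12 libraries by culture, with colour for genotype and symbol for line. T, Wnt3, Fgf8, Gsc, Cer1, Mixl1 and Foxa2 were higher in the WT FA libraries than in both KO FA libraries, and Gpx2 and Olig2 were higher in every KO library than in every WT library.

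When the cultures were averaged within each line, KO differed from WT in 165 genes, 73 higher and 92 lower. Gpx2, Olig2 and Cyct were higher in KO, with log2 fold changes of 3.70, adjusted p = 0.00284, 2.96, adjusted p = 0.00249 and 2.87, adjusted p = 0.00727 (limma on 4 line means). So were Ubd (log2 fold change 3.30) and Tstd1 (log2 fold change 2.81). Tagln (log2 fold change -3.96, adjusted p = 0.00162), Krt19 (log2 fold change -3.58, adjusted p = 0.00284) and Igfbp3 (log2 fold change -3.25, adjusted p = 0.00284) were lower. Zfp281 itself was lower by the same test (log2 fold change -3.20, SE 0.55, adjusted p = 0.0344). Lin28a fell (log2 fold change -2.65), Nes fell (log2 fold change -2.16) and Tet2 rose (log2 fold change 1.55). Tet1 was not called in any culture, at 3.47 ± 0.209 FPKM in WT SL and 5.39 ± 4.43 in KO SL (mean ± SD, n = 2). The Nodal feedback gene Lefty1 fell (log2 fold change -1.77), from 212 ± 64.1 to 57.0 ± 14.7 FPKM in SL, where it was not called by itself.

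By the camera test 7 lists passed across cultures, and none did so with an estimated correlation. Streak genes (adjusted p = 7.31e-08, or 0.331 with an estimated correlation), trophectoderm genes (adjusted p = 7.61e-05, or 0.331 with an estimated correlation) and fibroblast genes (adjusted p = 8.49e-05, or 0.331 with an estimated correlation) were lower in KO. Nodal genes (adjusted p = 0.00115, or 0.331 with an estimated correlation), primed genes (adjusted p = 0.00174, or 0.623 with an estimated correlation) and imprinted genes (adjusted p = 0.00763, or 0.331 with an estimated correlation) were lower too. Naive genes were higher (adjusted p = 0.0159, or 0.715 with an estimated correlation), with 0 of 15 members called and 2 when adjusted over the list alone. The naive call was lost without KO replicate 1, line 3.34-/- (adjusted p = 0.632), and without WT replicate 2 (0.276). The primed call was lost without WT replicate 1 (adjusted p = 0.174) and without KO replicate 1 (0.0585), and the imprinted call without WT replicate 1 (0.0741). Called members were T, Wnt3 and Fgf8 of 7 streak genes, Krt8 and Krt18 of 5 trophectoderm genes, Tagln, Acta2 and Col1a2 of 6 fibroblast genes, Lefty1 and Cer1 of 8 Nodal genes, H19 of 15 imprinted genes and 0 of 12 primed genes. Adjusted over the list alone, the calls numbered 5, 4, 3, 3, 4 and 2 in that order of streak, trophectoderm, fibroblast, Nodal, imprinted and primed genes.

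The calls of the separate cultures overlapped: 19 genes were higher and 23 lower in KO in all 3. Between SL and FA, 55 higher and 122 lower genes were shared, where independent lists would share 1.31 and 4.04. The same 4 lines were measured in each culture, so these overlaps include differences between lines. Genes higher in all 3 cultures, named after their values were seen, included Olig1 (log2 fold changes 2.52 in SL, 2.23 in 2iL and 2.64 in FA, in this order for the rest). Beside it stood the homeobox genes Vax2 (1.78, 1.93, 1.69) and Hesx1 (1.18, 1.88, 1.38). Metabolic and stress genes were Slc1a5 (2.18, 2.36, 3.19), the mitochondrial folate enzyme gene Mthfd2 (1.33, 1.77, 1.51) and the stress cytokine gene Gdf15 (1.40, 1.56, 2.36). Genes lower in all 3, chosen the same way, included Lin28a, T, Wnt3, Fgf8, Tagln, Car2 (-2.75, -2.45, -2.74), the growth cone gene Gap43 (-2.62, -1.43, -1.58) and the muscle intermediate filament gene Des (-1.27, -1.18, -1.23). None of the genes named by rule across cultures kept its call in all 15 alternatives. A sex-linked gene that the rule also named is not reported. With 4 line means the count rested on single lines: it was 0 without line CJ7 (WT replicate 1), 2 without line 3+/+ (WT replicate 2), 953 without line 3.34-/- (KO replicate 1) and 1552 without line 7-/- (KO replicate 2). The call of Zfp281 had an adjusted p of 2.80e-15 to 0.417 over the alternatives.

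The move of WT cells from SL to 2iL took away serum and added the MEK and Gsk3 inhibitors at once. The effects of these changes cannot be told apart in this comparison. Genes that act downstream of FGF and MAPK were among the falls. Etv4, an ETS factor gene, fell from 17.7 ± 4.51 to 0.0734 ± 0.0445 FPKM (mean ± SD, n = 2; log2 fold change -4.11, SE 0.38, adjusted p = 6.15e-04, limma). The phosphatase genes Dusp6 and Dusp4 fell, Dusp6 from 29.9 ± 3.07 to 0.874 ± 0.113 (log2 fold change -4.04, SE 0.58, adjusted p = 0.00444) and Dusp4 from 18.4 ± 1.83 to 0.699 ± 0.0322 (log2 fold change -3.51, adjusted p = 0.00285). Id1 and Id2, BMP-responsive genes, fell by log2 fold changes of -4.51, adjusted p = 2.55e-04 and -3.29, adjusted p = 0.00248. Hbb-bh1 rose from 0.785 ± 0.936 to 41.1 ± 9.28 FPKM (log2 fold change 4.65, adjusted p = 1.32e-04). Hbb-y rose from 0.0637 ± 0.0901 to 12.7 ± 0.253 (log2 fold change 3.69, adjusted p = 1.07e-05) and the channel gene Trpm1 from 1.07 ± 0.0298 to 44.2 ± 2.91 (log2 fold change 4.45, adjusted p = 1.47e-05).

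Further rises in WT 2iL were in the methionine cycle gene Bhmt (log2 fold change 3.42), the ETS factor gene Spic (log2 fold change 3.04), Pga5 (log2 fold change 3.02), Itpka (log2 fold change 2.94) and Pdlim4 (log2 fold change 2.87). Further falls were in Spink3 (log2 fold change -4.31), the lymphotoxin gene Ltb (log2 fold change -4.00) and Tagln (90.4 ± 8.35 to 7.67 ± 0.406 FPKM, -3.40). Camera passed 11 lists. FGF and MAPK targets fell (adjusted p = 2.60e-10, or 0.0322 with an estimated correlation), with 7 of 12 members called and 9 when adjusted over the list alone. Primed and formative genes fell (adjusted p = 3.91e-08, or 0.0876 with an estimated correlation), with Pou3f1 (9.69 ± 3.74 to 0.179 ± 0.0386 FPKM), Tcf15, Pim2 and Cldn6 the 4 called of 12, and 8 when adjusted over the list alone. General pluripotency genes fell (adjusted p = 3.25e-04, or 0.0322 with an estimated correlation), with Dppa2 and Lin28a called of 10, and 3 when adjusted over the list alone. Naive genes rose (adjusted p = 0.00737, or 0.415 with an estimated correlation), with Prdm14 (log2 fold change 1.73), Tfcp2l1 (log2 fold change 2.28) and Dppa3 (log2 fold change 2.37) called of 15, and 4 when adjusted over the list alone. Fibroblast genes (adjusted p = 2.24e-06, or 0.0289 with an estimated correlation) and imprinted genes (adjusted p = 2.99e-05, or 0.0289 with an estimated correlation) fell, with Tagln and Acta2 called of 6 and Nnat and Snrpn called of 15, and with 5 and 7 when adjusted over the list alone. Trophectoderm genes fell (adjusted p = 3.25e-04, or 0.0819 with an estimated correlation), with Krt8 and Krt18 called of 5, and 3 when adjusted over the list alone. Cholesterol biosynthesis genes rose as a list (adjusted p = 0.00437, or 0.126 with an estimated correlation). The p53 targets rose (adjusted p = 0.0203, or 0.217 with an estimated correlation), with Cdkn1a the 1 called of 11, and 2 when adjusted over the list alone. The list of 2-cell-like genes (adjusted p = 0.0237, or 0.377 with an estimated correlation) and glycolysis genes (adjusted p = 0.0388, or 0.314 with an estimated correlation) fell with 0 members called of 3 and 13, and with 0 and 2 when adjusted over the list alone. Dnmt3l fell from 200 ± 48.0 to 23.5 ± 3.75 FPKM (log2 fold change -3.02, adjusted p = 0.0209). Gsc rose from 0.536 ± 0.288 to 6.39 ± 2.48 (log2 fold change 2.24, adjusted p = 0.00813).

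Limma called 547 genes between 2iL and SL in WT, 228 higher and 319 lower in 2iL, and 1802 with the cell line as a block. The count was 119 without WT SL replicate 1, 114 without WT SL replicate 2, 101 without WT 2iL replicate 1 and 102 without WT 2iL replicate 2. Itpka and Pdlim4 lost their calls in at least 1 of these. The glycolysis call was lost with the block (adjusted p = 0.0512), with a pseudocount of 0.1 (0.0590), without WT SL replicate 1 (0.0706) and without WT 2iL replicate 2 (0.0858). The naive call was lost without WT SL replicate 2 (0.0750) and without WT 2iL replicate 1 (0.0534), and the 2-cell-like call without WT SL replicate 2 (0.0673).

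The move from SL to FA, in WT as in KO cells, took away serum and LIF and added activin A and Fgf2 at once. Effects of these changes cannot be told apart either. In WT cells moved from SL to FA, the largest rises were in mesendoderm genes. Gsc rose from 0.536 ± 0.288 to 9.60 ± 2.79 FPKM (mean ± SD, n = 2; log2 fold change 2.77, SE 0.36, adjusted p = 0.0255, limma) and Fgf8 from 1.85 ± 0.565 to 8.17 ± 2.24 (log2 fold change 1.68, SE 0.22, adjusted p = 0.0255). Cer1 was listed at 0 in both WT SL libraries and stood at 6.44 and 6.12 FPKM in the WT FA libraries (adjusted p = 1.88e-05). Fst, which encodes the activin-binding protein follistatin, rose (log2 fold change 1.54, adjusted p = 0.0309), and so did the peptide hormone gene Apln (log2 fold change 1.42, adjusted p = 0.0432). Id1 fell from 110 ± 10.5 to 4.06 ± 0.459 FPKM (log2 fold change -4.46, adjusted p = 9.34e-04), with Krt14 (log2 fold change -2.35, adjusted p = 0.0328), Mylpf (log2 fold change -2.15, adjusted p = 0.0328), Wnt6 (log2 fold change -2.07, adjusted p = 0.0127) and Npl (log2 fold change -1.71, adjusted p = 0.0458).

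Camera passed 9 lists in this comparison, and 3 kept their call with an estimated correlation. Streak genes rose (adjusted p = 2.88e-19, or 0.0115 with an estimated correlation), with Gsc, Foxa2, Fgf8 and Mixl1 the 4 called of 7, and all 7 when adjusted over the list alone. Cholesterol biosynthesis genes rose (adjusted p = 6.54e-15, or 0.0115 with an estimated correlation) with 0 of 18 members called and 8 when adjusted over the list alone, among them Insig1 (59.6 ± 9.80 and 150 ± 15.4 FPKM in SL and FA). Trophectoderm genes fell (adjusted p = 1.34e-06, or 0.0392 with an estimated correlation), with Cdx2 (log2 fold change -1.20) called of 5, and 4 when adjusted over the list alone. Naive genes fell as a list (adjusted p = 1.52e-04, or 0.250 with an estimated correlation) with 0 of 15 members called by either adjustment. Klf4 stood at 9.63 and 4.15 FPKM in SL and 6.89 and 2.46 in FA. LIF and STAT3 targets fell (adjusted p = 2.75e-06, or 0.223 with an estimated correlation) with 0 of 6 called and 2 when adjusted over the list alone, Socs3 and Junb. Primed genes (adjusted p = 3.74e-04, or 0.250 with an estimated correlation) and Nodal genes (adjusted p = 0.00718, or 0.113 with an estimated correlation) rose, with 0 of 12 and 1 of 8 members called, Cer1, and 1 each when adjusted over the list alone. The 2-cell-like list (adjusted p = 0.00281, or 0.250 with an estimated correlation) and glycolysis genes (adjusted p = 0.00718, or 0.237 with an estimated correlation) fell with 0 of 3 and 0 of 13 members called by either adjustment. Limma called 16 genes, 8 in each direction, where 549 had an unadjusted p below 0.05, and 87 with the cell line as a block. The count was 2 without WT SL replicate 1 or without WT SL replicate 2, 5 without WT FA replicate 1 and 6 without WT FA replicate 2, and of the genes named by rule only Id1 and Cer1 kept their call in all 15 alternatives. Without WT FA replicate 1 the primed list stood at adjusted p = 0.309 and the Nodal list at 0.194, and without WT SL replicate 2 the primed list stood at 0.0637.

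In KO cells moved from SL to 2iL, 4 of 12 FGF and MAPK genes were called lower, and the list's call was lost with an estimated correlation (adjusted p = 0.0725). Of the 4, Etv4 fell from 32.8 ± 3.63 to 0.702 ± 0.360 FPKM (mean ± SD, n = 2; log2 fold change -4.32, SE 0.38, adjusted p = 6.54e-04, limma). Dnmt3l fell from 143 ± 26.7 to 5.83 ± 6.41 (log2 fold change -4.80, SE 0.61, adjusted p = 0.00278). The trypsin inhibitor gene Spink3 fell from 68.9 ± 1.71 to 1.44 ± 0.422 (log2 fold change -4.85, adjusted p = 7.43e-04) and Id1 from 51.0 ± 10.9 to 2.07 ± 0.545 (log2 fold change -4.08, adjusted p = 5.48e-04). The hypoxia-inducible genes Bnip3 and Slc16a3 fell as well (log2 fold change -3.95, adjusted p = 0.00690 and -3.81, adjusted p = 0.00202), with Eras (log2 fold change -3.78) and Lypd2 (log2 fold change -3.50). Bnip3 stood at 358 and 88.5 FPKM in the KO SL libraries, highest in replicate 1. AA467197 rose from 4.03 ± 1.61 to 206 ± 97.9 FPKM (log2 fold change 5.31, adjusted p = 1.08e-04). Other rises were Trpm1 (log2 fold change 4.03), Bhmt (log2 fold change 3.69), Spic (log2 fold change 3.50), the water channel gene Aqp3 (log2 fold change 3.45), the surface antigen gene Ly6a (log2 fold change 3.66), S100a1 (log2 fold change 3.33) and S100a13 (log2 fold change 4.54).

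Camera passed 6 lists for 2iL against SL in KO, and none kept its call with an estimated correlation. General pluripotency genes fell (adjusted p = 1.33e-04, or 0.0725 with an estimated correlation), with Utf1, Lin28a and Dppa2 called of 10, and 6 when adjusted over the list alone. FGF and MAPK targets fell (adjusted p = 1.03e-06, or 0.0725 with an estimated correlation), with Etv4, Dusp6, Spry4 and Ier3 called of 12, and 9 when adjusted over the list alone. Glycolysis genes fell (adjusted p = 2.32e-05, or 0.0725 with an estimated correlation), with Pfkl called of 13, and 7 when adjusted over the list alone. Of these, Ldha stood at 2865 and 1042 FPKM in SL and 607 and 324 in 2iL. Primed genes (adjusted p = 0.0182, or 0.594 with an estimated correlation) and imprinted genes (adjusted p = 0.00298, or 0.0725 with an estimated correlation) fell, with Tcf15 and Cldn6 called lower of 12, and Nnat and Snrpn called lower and Igf2r higher of 15. Adjusted over the list alone, 2 primed and 5 imprinted genes were lower. Cholesterol biosynthesis genes rose as a list (adjusted p = 0.0225, or 0.244 with an estimated correlation). Gsc, outside the passing lists, rose from 0.784 ± 0.210 to 14.4 ± 5.57 FPKM (log2 fold change 3.06, adjusted p = 0.00200). Limma called 644 genes, 391 higher and 253 lower in 2iL, and 2382 with the cell line as a block. Since the spread per gene was shared with the WT lines, which lay closer together, the count of 644 can be too high. The count was 239 without KO SL replicate 1 and 190 without KO 2iL replicate 1, and with only the KO SL and KO 2iL libraries in the fit it was 7. Of the 16 genes named by rule, 10 lost their call there or without 1 library. Without KO SL replicate 2 the primed, cholesterol and imprinted lists stood at adjusted p = 0.225, 0.235 and 0.102. The primed call was also lost without KO 2iL replicate 2 (0.186), and the cholesterol call without KO 2iL replicate 1 (0.0569).

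In KO cells moved from SL to FA, Fads2, a fatty acid desaturase gene, rose from 6.97 ± 2.93 to 37.3 ± 3.57 FPKM (mean ± SD, n = 2; log2 fold change 2.31, SE 0.33, adjusted p = 0.0338, limma). The sterol transporter gene Abcg1 rose from 5.73 ± 2.26 to 25.3 ± 3.96 (log2 fold change 2.00, SE 0.30, adjusted p = 0.0338). Socs3, a LIF target gene, fell from 50.8 ± 1.20 to 6.14 ± 4.98 FPKM (log2 fold change -3.06, adjusted p = 0.0359). Id1 fell from 51.0 ± 10.9 to 5.91 ± 3.73 (log2 fold change -3.01, adjusted p = 0.0157) and Spink3 from 68.9 ± 1.71 to 6.04 ± 5.11 (log2 fold change -3.53, adjusted p = 0.0209). Gdf15, Slc1a4, Rbpms2, Ctxn3, Tmem63a and Rad50 rose (1.70, 1.27, 1.99, 1.58, 1.42 and 1.40). Mylpf, Hal, Plac8, Ankrd37 and Eras fell (-2.72, -2.69, -2.48, -2.44 and -2.29). Camera passed 3 lists, none with an estimated correlation. Primed genes rose as a list (adjusted p = 4.51e-04, or 0.592 with an estimated correlation) with 0 of 12 members called and 5 when adjusted over the list alone, among them Otx2 (8.68 and 7.14 FPKM in SL and 26.8 and 41.0 in FA). Cholesterol biosynthesis genes rose (adjusted p = 2.91e-05, or 0.168 with an estimated correlation) and glycolysis genes fell (adjusted p = 0.00533, or 0.487 with an estimated correlation), with 0 of 18 and 0 of 13 called, and 4 and 2 when adjusted over the list alone. The streak list was not called (adjusted p = 0.609). Limma called 30 genes, 12 higher and 18 lower in FA, where 1697 had an unadjusted p below 0.05, and 770 with the cell line as a block. The count was 3 without KO SL replicate 1, 10 without KO FA replicate 2, 70 without KO FA replicate 1 and 213 without KO SL replicate 2. None of the genes named by rule kept its call in all 15 alternatives. Without KO FA replicate 2 the primed list stood at adjusted p = 0.216 and the glycolysis list at 0.143. The glycolysis call was also lost without KO SL replicate 1 (0.0945), the library rich in Rmrp and Rpph1.

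**Figure D3:**
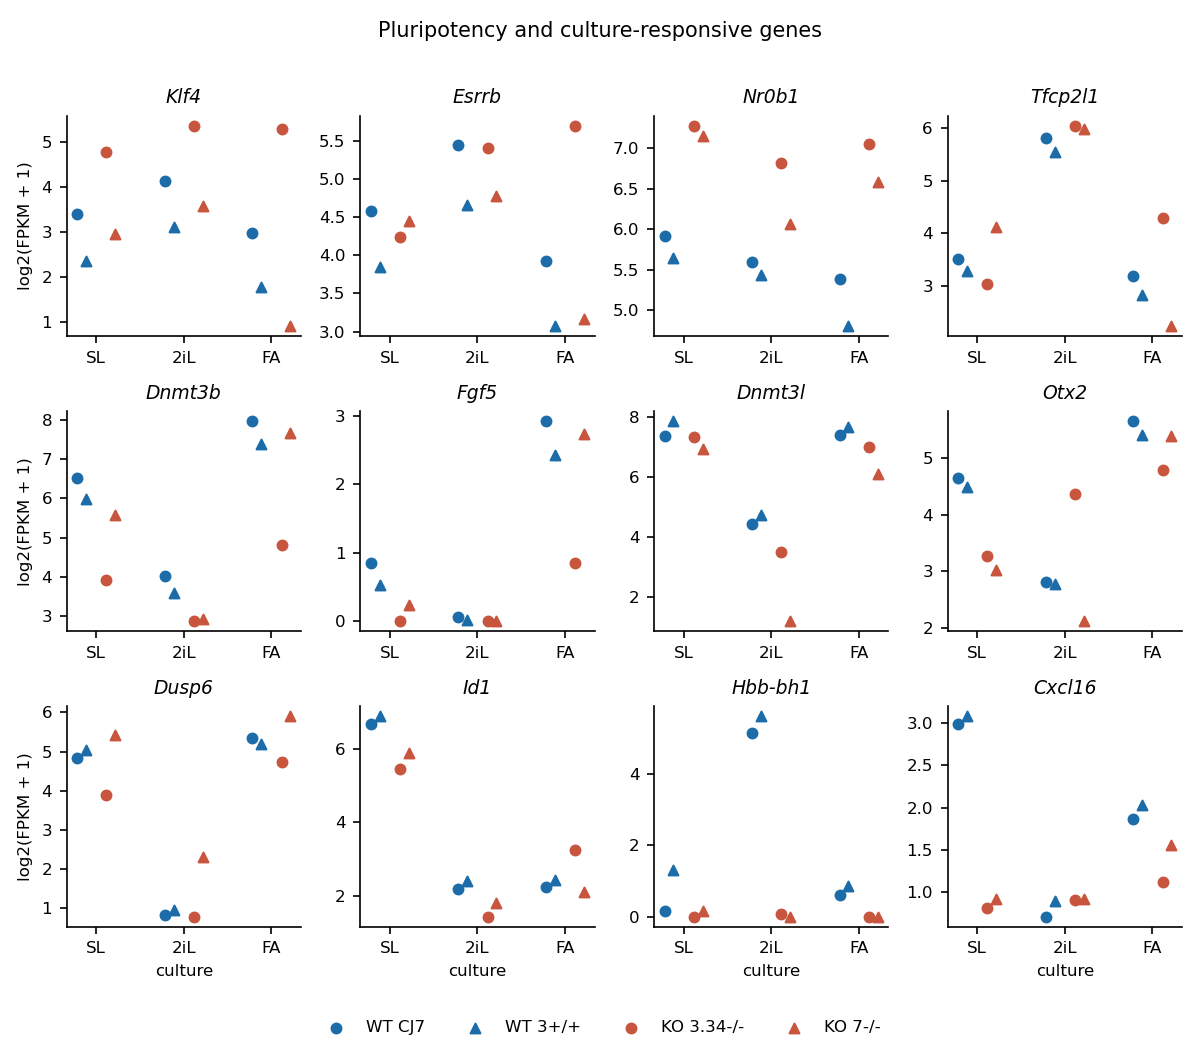
Each panel plots log2(FPKM + 1) of 1 gene in the 12 libraries by culture, with colour for genotype and symbol for line. Dusp6 was lower in every 2iL library than in the SL libraries, Klf4 and Esrrb in FA were higher in line 3.34-/- than in line 7-/-, and Hbb-bh1 was high in the WT 2iL libraries alone.

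Whether KO cells answered a culture differently from WT cells was tested as the difference between the genotypes' changes. For 2iL against SL the difference was called for 6 genes. Hbb-bh1 changed by 4.65 in WT, and the difference, KO minus WT, was log2 fold change -4.69, SE 0.45, adjusted p = 0.00650 (limma). Hbb-y gave -3.85, adjusted p = 2.12e-04. Hba-a1 with Hba-a2, a joint feature outside the naming rule and chosen after its values were seen, gave -2.03, adjusted p = 0.0309. Acta1, Tagln and the chemokine gene Cxcl16 gave positive differences of 3.18, adjusted p = 0.0133, 2.63, adjusted p = 0.0268 and 2.27, adjusted p = 0.0284. Tagln fell by a log2 fold change of -3.40 in WT, where it was high in SL, against -0.76 in KO, where it was already low. Acta1, Krt8 and Krt18 were likewise already lower in KO than in WT in SL. Prss23, AA467197, Bcl2l15, Rab25 and Ass1, the next by rule, were not called, with adjusted p of 0.0580, 0.0602, 0.224, 0.232 and 0.337. Of the lists, trophectoderm (adjusted p = 4.17e-06, or 0.0592 with an estimated correlation) and fibroblast genes (adjusted p = 3.55e-04, or 0.0592 with an estimated correlation) differed upward. So did primed (adjusted p = 0.00118, or 0.556 with an estimated correlation) and germline genes (adjusted p = 0.00985, or 0.556 with an estimated correlation). Glycolysis genes differed downward (adjusted p = 5.82e-04, or 0.186 with an estimated correlation). Among the members, Tagln was the 1 fibroblast gene called of 6, and 0 were called in the other 4 lists. Adjusted over the list alone the calls were 4 trophectoderm, 2 fibroblast and 1 primed gene. The germline call was lost without any 1 of 4 libraries (adjusted p 0.0819 to 0.220), and the fibroblast call without KO SL replicate 2 (0.0883). The changes of the genotypes correlated across genes (Pearson's r = 0.616, Spearman's rho = 0.594, 11584 genes that are not independent replicates). In both, 137 higher and 105 lower genes were called, where independent lists would share 7.70 and 6.97. The count of 6 stood beside 546 genes with an unadjusted p below 0.05, was 72 with the cell line as a block, and ran from 1 (without KO SL replicate 1) to 11 (without KO 2iL replicate 2). With a pseudocount of 0.1 it was 0, and none of the 5 named calls held in all 19 alternatives. With the block, AA467197, Prss23 and Ass1 were called as well, at adjusted p of 0.0173, 0.0235 and 0.0408. Of the 72 calls with the block, 64 were positive and 8 negative, against 3 and 3 without it.

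For FA against SL the difference was called for 3 features. Cer1 was listed at 0 in all 4 SL libraries, at 6.44 and 6.12 FPKM in WT FA and at 0.0203 and 0 in KO FA (adjusted p = 2.90e-04, limma), and held in all 19 alternatives. The other 2 are microRNA gene features outside the naming rule, chosen after their values were seen: Mir669i (log2 fold change -6.92, adjusted p = 6.76e-04) and Mir1192 (log2 fold change 5.54, adjusted p = 6.25e-06). Other microRNA features were listed at 0 in some libraries and at 1000 FPKM or more in others, so values of this kind can be failed estimates. Gsc, whose mean went from 0.536 ± 0.288 to 9.60 ± 2.79 FPKM in WT and from 0.784 ± 0.210 to 0.292 ± 0.413 in KO, was not called (adjusted p = 0.179) but was called with the cell line as a block, at 0.00282. Fgf8, Fst, Apln, Tagln, Cxcl16, Acta1, Acot2 and Wnt6, the next by rule, were not called, at adjusted p of 0.667, 0.843, 0.980, 0.422, 0.422, 0.667, 0.667 and 0.714. Streak genes differed downward as a list (adjusted p = 2.60e-11, or 0.0754 with an estimated correlation) with 0 of 7 members called and 5 when adjusted over the list alone. Trophectoderm genes differed upward (adjusted p = 8.40e-06, or 0.0754 with an estimated correlation) with 0 of 5 and 4. In WT, Cdx2, Krt7, Krt8 and Krt18 were lower in FA than in SL (log2 fold changes -1.20, -0.83, -1.20 and -1.24). These genes were already lower in KO than in WT in SL. The KO SL levels of Krt8 and Krt18 still allowed a fall of that size, and whether a lower start limited the falls was not tested. The Nodal list, not called, had a median difference of 0.13 and a mean of -0.15, and its test pointed down (adjusted p = 0.342). Across genes the changes correlated with Pearson's r = 0.407 and Spearman's rho = 0.392. Of the calls, 0 higher and 4 lower genes were called in both genotypes. The count of 3 stood beside 293 genes with an unadjusted p below 0.05, was 5 with the cell line as a block, and reached 8 without KO FA replicate 1.

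**Figure D4:**
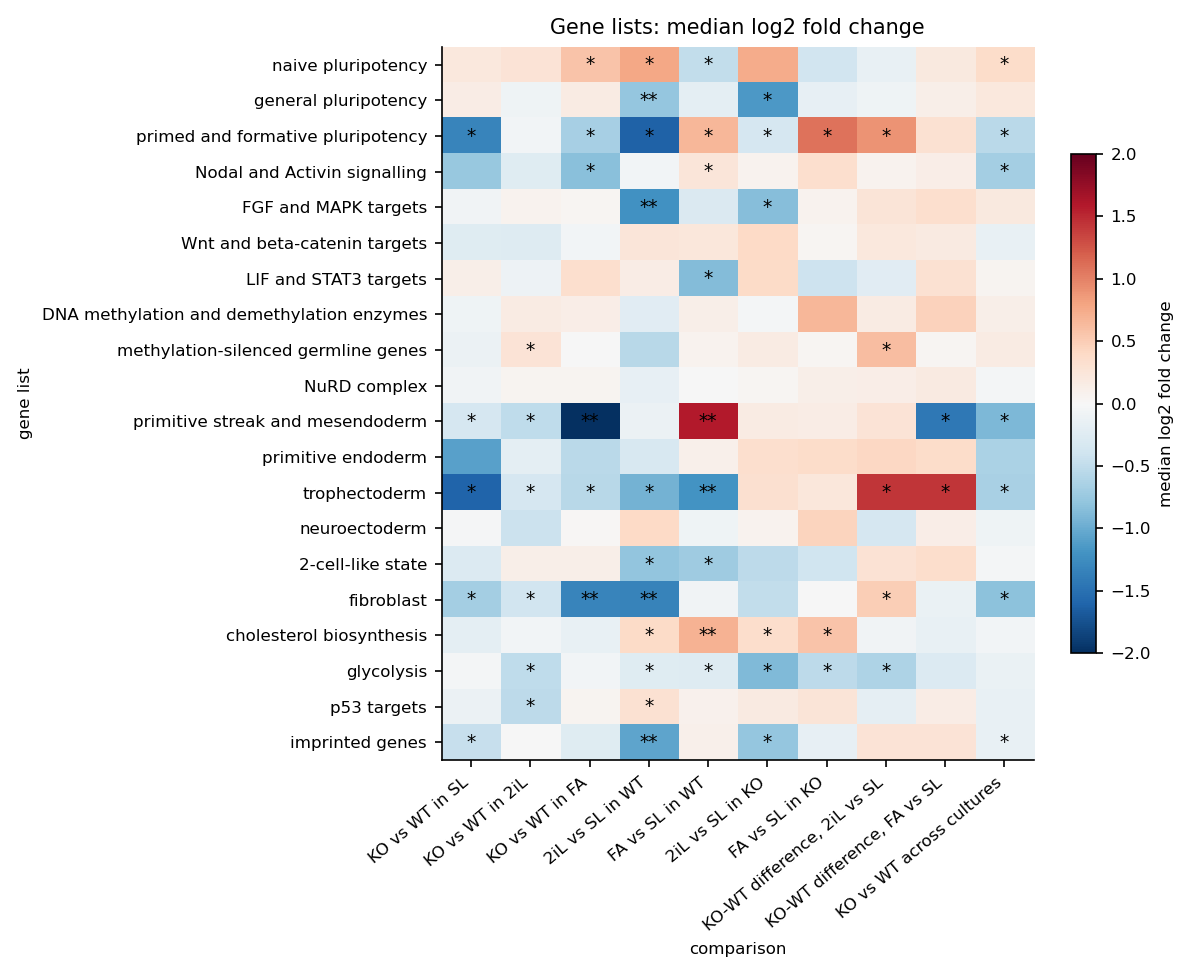
Colour gives the median log2 fold change of each of the 20 lists in each of the 10 comparisons. A star marks an adjusted p below 0.05 by camera, and a double star the same with an estimated correlation as well, as for streak genes in KO against WT in FA. The median, the mean and the test's direction differed in sign in 26.0 of the 200 list tests, 0 of them called.

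EpiSC and long-term 2iL cells, with 1 library each of different lines, give the primed and naive ends against which the 48 h changes can be set, without a replicate check. Gbp2, Tagln and Igfbp3, all lower in KO SL cells, were among the genes with the largest excess in EpiSC, at 102, 127 and 189 FPKM against 0.0557, 0.673 and 1.79 in long-term 2iL. Slc39a8, S100a6 and Dok2 were also among them, at 59.0, 472 and 49.2 FPKM against 0.131, 8.88 and 0.0543. Pkdcc and the chemokine gene Ccl20 stood at 54.9 and 52.9 FPKM in EpiSC and were listed at 0 in long-term 2iL. Dppa5a, Tdh, Zfp42 (Rex1) and Dazl had the reverse pattern, at 2600, 426, 398 and 121 FPKM in long-term 2iL against 4.45, 0.992, 1.87 and 0.0566 in EpiSC, with Rpl39l, Rpl10l, Crxos1 and the autosomal gene Rps4y2 beside them. The naive list's median log2 difference, EpiSC minus long-term 2iL, was -4.92, below all of 10000 random lists matched on size and expression. The primed list's was 1.99, above 100% of the random lists, and the streak list's 1.82, also above 100%. The same difference correlated with the 48 h change from 2iL to FA at r = 0.553 in WT (rho = 0.548; 0.588 and 0.466 by line) and 0.410 in KO (rho = 0.373; 0.335 and 0.400 by line), across 11584 genes that are not independent replicates. The streak list's median change from 2iL to FA was 1.51 in WT and -0.02 in KO. At least 2-fold differences numbered 1299 genes higher in EpiSC and 1631 higher in long-term 2iL.

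**Figure D5:**
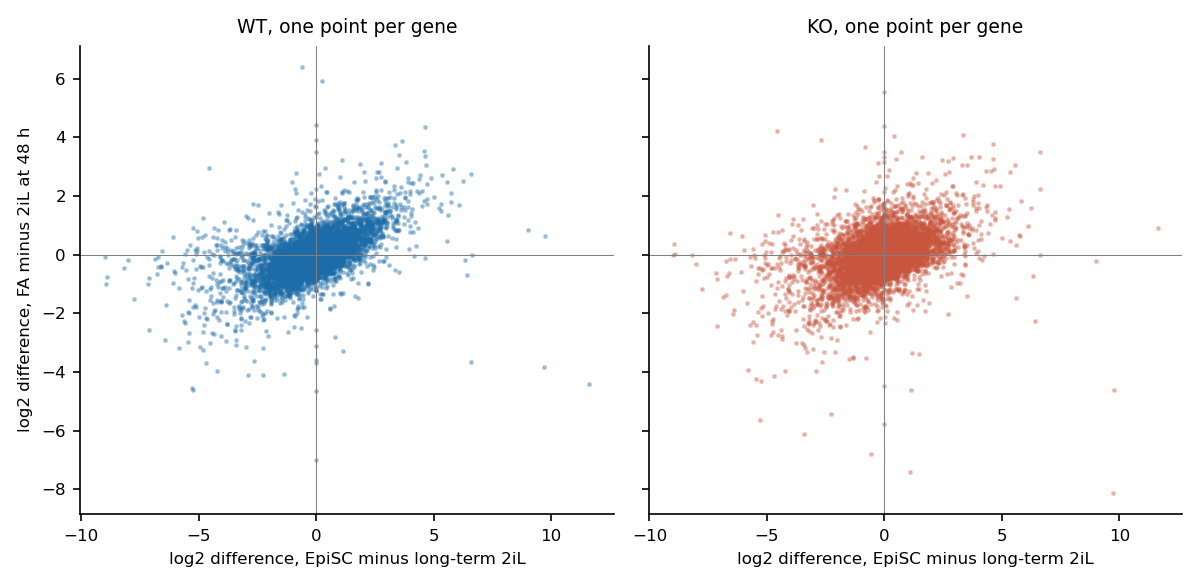
Each point is 1 gene. The x axis is the log2 difference of FPKM + 1 between the EpiSC and the long-term 2iL library, and the y axis is the change from 2iL to FA at 48 h, in WT (left) and KO (right). Pearson's r was 0.553 in WT and 0.410 in KO.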

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

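The tests of the abundance of fibroblast genes, of a single WT line, of the differences between the KO lines and of alpha-type globins were chosen only after the result was seen.

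The results below stood out because the change with culture differed between KO and WT in the test of that difference (limma, adjusted p below 0.05). For 2iL against SL the log2 differences, KO minus WT, were -4.69 for Hbb-bh1, -3.85 for Hbb-y, -2.03 for the joint feature Hba-a1 and Hba-a2, 3.18 for Acta1, 2.63 for Tagln and 2.27 for Cxcl16. For FA against SL they were -2.85 for Cer1, whose SL libraries were all listed at 0, 5.54 for Mir1192 and -6.92 for Mir669i. The last 2 are microRNA features, whose values can be failed estimates. Of the lists, primed and formative genes differed by a median of 0.89 for 2iL against SL, germline genes by 0.62, trophectoderm genes by 1.42, fibroblast genes by 0.49 and glycolysis genes by -0.62. For FA against SL, primitive streak genes differed by a median of -1.43 and trophectoderm genes by 1.43. Tagln, Acta1, Krt8 and Krt18 were already lower in KO than in WT in SL. Tagln and Acta1 stood near or below 1 FPKM in KO SL, which left them little room to fall. Krt8 and Krt18 stood higher, and whether their lower start limited their fall was not tested. The upward differences of Tagln and Acta1 therefore need not be a different answer to the culture. For the trophectoderm list this cannot be told. With an estimated correlation none of these list differences was called, at adjusted p of 0.0592 to 0.556 for 2iL and 0.0754 for both in FA.

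Tagln, Acta1, Cnn1, Krt8 and Krt18 fell in the KO SL libraries, by a median log2 difference of -3.96. Fibroblasts or other collagen-making cells present in the WT cultures alone would bring collagens with them, yet 7 fibroblast genes together came to 4.15% of Tagln at most in the WT SL libraries. Their fold changes, which were to be tested, decide nothing at so low a level. A difference in scaling between libraries is argued against as well, since median-ratio scaling gave -4.01. A lower level of primed, epiblast-like transcription in KO stays open as a hypothesis found and tested on the same data: all 5 genes were higher in the EpiSC library than in the long-term 2iL library. Against it, Tagln, Krt8 and Krt18 were lower in WT FA than in WT SL, by log2 fold changes of -0.90, -1.20 and -1.24, none of them called. Line background stays open beside this hypothesis, since genotype and line coincide.

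Hbb-bh1 and Hbb-y rose in WT and not in KO from SL to 2iL. Primitive red blood cells in the WT cultures would carry alpha-type globins at a level like that of the beta-type, but these came to 8.96% at most in the WT 2iL libraries. The most abundant of 6 red cell genes came to 0.760% of Hbb-bh1 in WT 2iL, by group means. Their median log2 change of 0.07 decides nothing at so low a level. A property of the CJ7 line alone is argued against by line 3+/+, where the lower of the 2 genes' log2 changes was 3.80. Reads shared between globin genes stay open, since Hbb-b1 and Hbb-b2, which were to decide it, were listed at 0 (0% of Hbb-bh1) in all 14 libraries, and a 0 can be a failed estimate, as for Eef1a1 in 4 libraries. Also open is a property that both WT lines share and both KO lines lack, with or without Zfp281 as its source, and no biological explanation was tested.

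The KO lines differed in FA, where primed genes were near WT in line 7-/- and low in line 3.34-/-. An exchange of the line 7-/- FA library with a WT FA library is argued against by its Zfp281, 19.4% of the lowest WT FA library, and an exchange of the FA and 2iL libraries of line 3.34-/- by its FGF and MAPK genes, which were higher in FA by a median log2 difference of 0.889 (median absolute deviation 0.820). The Zfp281 transcript left in line 7-/- stays open: over the 378 genes called in SL, the lines' median distances from WT differed by -0.0109 to 0.159, but calls in SL need the lines to agree, so this decides nothing. Another property of line 3.34-/- stays open as well, since the primed list's median difference between the lines was -0.997 in FA but -0.388 and 0.0311 in SL and 2iL. The last has the sign that this explanation forbids, but its SE over 12 genes was 0.243.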

How the results depend on the processing

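Leaving out features with failed estimates, the list tests without each library and the correlations by single line were chosen only after the data were seen; every alternative set beforehand was run. No gene called in any comparison changed its sign under any alternative. Of 5045 alternative values of named genes, 4121 kept their side of the threshold, 916 lost a call, 8 gained one and 0 reversed. Where a fit left 1 library in a group, that library was assumed to vary like the other groups. Depth is known only as a ratio, so what depth limits could not be computed. Unless fewer libraries or another number of genes tested shows it, the cause was not tested.

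Without a filter on low values the counts were 651 for KO against WT in SL, 512 in FA, 828 for WT 2iL against SL, 85 for WT FA against SL, 62 and 6 for the differences in 2iL and FA, and 0 across cultures. A pseudocount of 0.1 gave 2 for WT FA against SL and 0 for the difference in 2iL, quantile normalization 15 for that difference, leaving out small RNAs 1 for the difference in FA, and eBayes without trend 92 across cultures. With only the libraries compared, the counts were 180, 67 and 83 for KO against WT in SL, 2iL and FA, 1554 and 4 for 2iL and FA against SL in WT, and 7 and 5 in KO. For 2iL against SL the shared fit had called 547 genes in WT and 644 in KO. These counts therefore do not rank the responses of the genotypes. All 12 libraries in one fit gave 1520 across cultures, since the libraries of a line then count as replicates. With an estimated correlation the numbers of lists called were 0 and 0 for KO against WT in SL and 2iL, 2 in FA, 4 and 3 for 2iL and FA in WT, 0 and 0 in KO, 0 and 0 for the differences and 0 across cultures.

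The same cell line links the libraries of a genotype: deviations from group means correlated at 0.409 to 0.718 within a line and at 0.00548 to 0.371 between lines that share only a number. With the line as a block the counts were 1802 and 87 for 2iL and FA against SL in WT, 2382 and 770 in KO, and 72 and 5 for the differences. For KO against WT the number is only shared, and a replicate block gave 752, 234 and 875 in SL, 2iL and FA and 437 across cultures.

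Without 1 library the counts ran from 56 to 562 for KO against WT in SL, 12 to 86 in 2iL and 77 to 577 in FA, from 101 to 119 and 2 to 6 for 2iL and FA in WT, from 190 to 857 and 3 to 213 in KO, from 1 to 11 and 3 to 8 for the differences, and from 0 to 1552 across cultures without 1 line. The numbers of lists called ran from 5 to 8 in SL, 4 to 7 in 2iL and 3 to 7 in FA, 9 to 11 and 8 to 9 for 2iL and FA in WT, 3 to 7 and 1 to 7 in KO, 3 to 5 and 2 to 6 for the differences, and 5 to 9 across cultures. The correlation with the EpiSC difference ran from 0.466 to 0.588 by line in WT and from 0.335 to 0.400 in KO. One list reversed: without KO FA replicate 1 the naive list in KO against WT in FA had a signed -log10 adjusted p of -0.126, against 6.30 without KO FA replicate 2.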

Other observations

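The hypoxia-inducible genes below and the correlation of each library with the EpiSC difference were chosen only after the data were seen. Of the genes of the NuRD chromatin complex, a fixed list, 0 of 12 members were called in KO against WT in SL, 2iL or FA, and the list's median log2 fold changes were -0.07, 0.05 and 0.05; changes near 2-fold would mostly be missed. Targets of Wnt and beta-catenin were not called as a list in any culture change, with medians of 0.24 in WT and 0.40 in KO for 2iL against SL, although 2iL holds a Gsk3 inhibitor. Cdx1 was its 1 member called in KO (log2 fold change 1.39, SE 0.23, adjusted p = 0.00933, limma). Axin2 passed in both genotypes when adjusted over the list alone, at 1.00 ± 0.422 FPKM in WT SL, 3.04 ± 1.15 in WT 2iL, 0.778 ± 0.517 in KO SL and 2.56 ± 0.414 in KO 2iL (mean ± SD, n = 2). Primitive endoderm genes were not called as a list in KO against WT in SL (adjusted p = 0.0708), with the basement membrane collagen gene Col4a1 at 6.84 ± 1.61 FPKM in WT and 2.58 ± 1.84 in KO.

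The hypoxia-inducible genes Bnip3, Slc16a3 and Ankrd37, the first 2 named for 2iL and the third for FA against SL in KO, differed between the KO SL libraries. Bnip3 was 358 FPKM in line 3.34-/- and 88.5 in line 7-/-, Slc16a3 158 and 79.0, and Ankrd37 48.3 and 28.9; the WT SL libraries held 59.5 and 88.8, 136 and 144 and 22.5 and 27.9. Each library's deviation from the mean of the 12 correlated across genes with the EpiSC minus long-term 2iL difference at 0.367 and 0.356 in the WT SL libraries, 0.461 and 0.276 in WT FA and -0.345 and -0.338 in WT 2iL. In KO the values for lines 3.34-/- and 7-/- were -0.0723 and 0.0919 in SL, -0.0282 and 0.210 in FA and -0.425 and -0.366 in 2iL.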
